A study of Mus musculus with 6 samples.

How the data were processed

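Total RNA from splenic cells of 6 mice was measured on an Illumina mouse BeadArray. The labels put 3 mice in the B6 wild-type group and 3 in the TLR7tg group. Each mouse has its own identifier, so that the p-values of the probe tests measure the spread between mice. Replicates were numbered within a group only as names. Per the labels' protocols, RNA was extracted with Trizol, its quality was tested by electrophoresis, and biotin-labelled cRNA was made with the TotalPrep kit. The way the cells were isolated is not given in the sources used here. The labels of single samples call the B6 cells NK cells and the TLR7tg cells NK1.1+ cells, while the design text of the series names NK1.1+ cells for both. The title of TLR7tg replicate 1 carries the identifier of B6 replicate 1, and its other labels carry a different one. Groups were taken from the strain or line in the labels.

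The deposited value table holds log2 values of 45281 probes in the 6 mice. After sorting, its columns differ by at most 0.0085, with a lowest value of 6.10, a median of 6.72 and a highest value of 15.09, as quantile normalisation without background subtraction would leave them. The tool behind the deposited log2 values is not given in the sources used here. For replicate 1 of each group the deposited value is an average of 2 technical arrays, per the labels. In these 2 mice the deposited values followed the mean log2 scanner signal of the named arrays in rank (Spearman correlation across probes 1.00 in each), which settles direction there but not scale. Their Pearson correlation was 0.989 (B6) and 0.980 (TLR7tg) with the log2 signals and 0.697 and 0.782 with the linear signals. The log2 signals had medians of 6.72 and 7.09 and a highest value of 16.13, and natural logarithms would have medians of 4.66 and 4.92 and a highest value of 11.18, so the values were read as log2. The slope on the log2 signals was 0.706 and 0.601, so the deposited scale is narrower than that of the raw signals, and fold values hold on the deposited scale only. The same scale is assumed for the other 4 mice. These tests of scale were added after the results were seen.

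The deposited scanner table gives a linear probe intensity per array, which its values show to be neither normalised nor background-subtracted. It also gives a detection p-value per probe and array, per the file headers. Its arrays come from 2 slides, and the 4 arrays used are those that the labels of replicate 1 of each group name. The other 8 columns, 4 of signal and 4 of detection p-values, match the labels of no mouse and were not used in any step. The design fixed before the data were examined was background correction and normalisation of the scanner signals of all 6 mice. Since the arrays of 4 mice could not be assigned, the deposited log2 values were tested as they are. Without background correction, log2 differences of dim genes are understated.

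The detection level was placed at 6.9 on the deposited log2 scale. In each bin of 0.1 from there upward, at least 95% of probes had a mean detection p-value under 0.05 in both mice with named arrays. Probes at or above 6.9 in at least 3 of the 6 mice were kept, 16535 in all. By detection p-value, 40.9% of probes were detected in B6 replicate 1 and 42.1% in TLR7tg replicate 1. The technical arrays of one mouse differed by a median of 0.0558 (B6) and 0.0515 (TLR7tg) on the log2 scale, and the median SD between mice was 0.211 in B6 and 0.258 in TLR7tg. With 1 value per mouse and 3 mice per group, the number of arrays limits the precision.

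Gene names came from the platform annotation. It gave 1 symbol for 34885 probes, several for 18 and none for 10378. Gene identifiers of 34807 probes matched the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. Of the kept probes, 13926 had 1 gene and 2609 were left unnamed, 339 of them past the threshold. Each of the 9173 genes was read through its brightest kept probe. For 2 genes, Ptpre and Acp2, another kept probe differed in the opposite direction.

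Probes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment over the kept probes and a threshold of 0.05. Differences are TLR7tg minus B6. Gene lists were tested with limma's camera at its preset correlation of 0.01, and beside it with an estimated correlation and with fry, each adjusted over the 29 lists. Camera compares a list with the other genes, while fry tests whether a list's genes move, on balance, one way. At the preset correlation camera takes a list's genes as nearly independent, so that its p-values do not measure the spread between mice. A gene below 6.9 in all mice of a group has only a bound there and is given as "at least N-fold", the mean of the brighter group set against 6.9.

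The lists and the rule for named genes were fixed before the data were examined. The rule took Tlr7, the 12 largest rises and 12 largest falls among genes past the threshold whose groups do not overlap (without placeholder symbols and sex-linked genes), up to 4 members per list with the smallest adjusted p among those past the threshold (or the 2 brightest where none passed), and a fixed set of NK, lymphoid and myeloid genes. Other genes are marked as chosen after their values were seen. Of the fixed set, Gzma, Cd79a and Mki67 were not analysed here, since no probe carries their symbol, and 1 other gene is not reported here. The probes of Gzmb and Ifit1 lay below the detection level (at most 6.59 and 6.71).

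The method was tested on 10 simulated tables of 16535 probes with 200 changed probes. At a log2 difference of 2, 99.6% were recovered, at a difference of 1, 59.2% were recovered, and 5.87% of calls were false. In a table with 1 shifted list, camera called that list and 1 of 28 unshifted lists. The simulated noise was independent between probes, while correlations estimated within lists ran from -0.29 (sex-linked genes) to 0.58 (Ly49 receptors). The simulation therefore does not test camera, or the share of false calls, among correlated genes. Neighbouring mouse identifiers pair each B6 mouse with a TLR7tg mouse. Deviations from the group means correlated across probes at 0.63, 0.12 and 0.45 within these pairs. Between other B6 and TLR7tg mice the correlations ran from -0.56 to 0.21, the highest being that of B6 replicate 3 and TLR7tg replicate 2. The labels state no shared litter, batch or day, and this block was kept as an alternative. The other alternatives were normexp on the deposited values, other filters on dim probes (no filter, detection in all 6 mice, and a raised filter at 7.9 in 3 mice), the first technical array alone, a trended and robust fit, array weights, the mean of a gene's probes, the slide as a block (which takes the 4 mice without named arrays as one) and leaving out each mouse.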

Results

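The study compared gene expression in splenic cells of C57BL/6 (B6) wild-type mice and of TLR7tg mice. The latter carry a Tlr7 transgene and serve as a model of systemic lupus erythematosus. The design text names NK1.1+ cells for both groups, while the labels of single samples name NK cells for B6. NK1.1, encoded by Klrb1c, is a surface receptor that marks natural killer (NK) cells in this strain. There were 3 mice per group. Signals are normalised log2 values, and 9173 genes had a probe above the detection level in at least 3 mice.

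Tlr7, the endosomal receptor for single-stranded RNA that the transgene encodes, was higher in all 3 TLR7tg mice than in any B6 mouse. Its signal on the 1 Tlr7 probe was 9.13 ± 0.57 (SD, n = 3) in B6 and 13.80 ± 0.71 (SD, n = 3) in TLR7tg, a difference of 4.67 (SE 0.38, limma adjusted p = 0.000248), or 25.4-fold. Between the 2 mice of the slide named in the labels the difference was 4.56, and among the other 4 mice it was 4.72. Of the genes near Tlr7 on chromosome X, Tlr8, another RNA sensor, rose by 1.75 (adjusted p = 0.00798), while Tmsb4x (-0.35) and Prps2 (0.21), chosen after their values were seen, did not pass. The call of Tlr8 ended without a filter on dim probes (adjusted p = 0.0567, and from 0.00347 to 0.0567 over its alternatives). In this list of 4 measured genes, which include the transgene Tlr7 itself, 2 rose, also when adjusted over the list alone. The list was higher by camera (adjusted p = 0.0208, and adjusted p = 0.367 with an estimated correlation), a call that rests in part on Tlr7. That call ended where detection in all 6 mice was required (adjusted p = 0.122, and from 0.00612 to 0.122 over its alternatives). The list's median was 0.98, and 0.21 in that setting and 0.13 without a filter.

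In TLR7tg cells most NK identity genes and Ly49 receptors and part of the T cell markers fell, and most neutrophil markers and part of the monocyte, Toll-like receptor signalling and interferon-stimulated genes rose. The largest falls among genes whose groups did not overlap were those of Klra4 (-5.07), Klra7 (-4.95) and Klra3 (-4.89), and the largest rises those of S100a8 (5.07), Ltf (4.81) and S100a9 (4.73). In all, 710 genes rose, 639 fell and 7824 did not pass, and 847 changed at least 2-fold (493 up, 354 down). The groups did not overlap in 2997 genes, 32.7% of those measured, where chance gives 10%. The count of genes higher in TLR7tg was 422 without B6 replicate 2, 459 without a filter on dim probes and 1118 with neighbouring mouse identifiers as a block. That of genes lower in TLR7tg was 340 without B6 replicate 2, 412 without B6 replicate 3, 1166 with the identifier block and 1083 with the slide as a block. The 4 mice other than those of the named slide alone gave 643 higher and 547 lower genes.

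**Figure D1:**
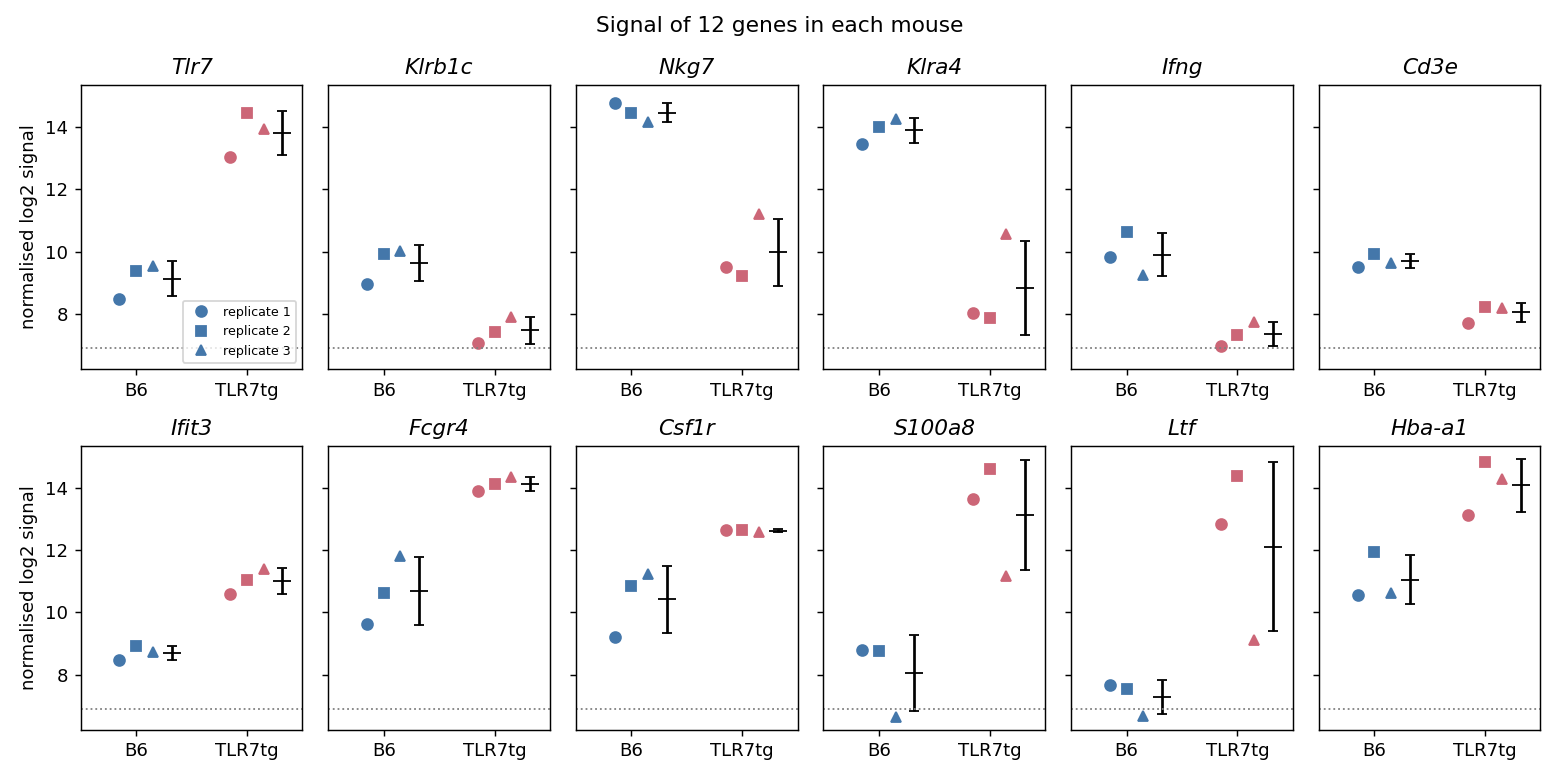
Normalised log2 signal (y axis) of 12 genes in each mouse, with B6 in blue and TLR7tg in red, the symbol's shape giving the replicate, black bars the group mean ± SD (n = 3) and the dotted line the detection level of 6.9. Tlr7 lay between 13.04 and 14.45 in TLR7tg and between 8.48 and 9.53 in B6, and Ltf ranged from 9.11 to 14.37 within TLR7tg.

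NK cell identity genes were lower nearly throughout. Of 22 measured members 21 fell, also when adjusted over the list alone, and Cd244a (-0.42, chosen after its values were seen) did not pass. Nkg7, a protein of cytotoxic granule membranes, was 14.46 ± 0.31 (SD, n = 3) in B6 and 9.98 ± 1.08 (SD, n = 3) in TLR7tg, and fell by 4.47 (SE 0.46). The lectin-like receptor Klre1 fell by 4.54 (SE 0.45), Klrd1, the CD94 partner of NKG2 receptors, fell by 3.86 and Klrk1, which encodes NKG2D, fell by 3.38. The NK transcription factor Eomes lay below the detection level in all TLR7tg mice and was at least 5.36-fold lower, and Tbx21, encoding T-bet, fell by 2.90. Klrb1c, the gene of NK1.1 itself, fell by 2.17 (SE 0.32, adjusted p = 0.00258) to 7.47 ± 0.42 (SD, n = 3), and Ncr1, encoding NKp46, was at least 1.48-fold lower. The list's median difference was -2.45 (-2.39 with genes at their bound), -2.60 within the named slide and -2.37 among the other 4 mice. Camera called it lower (adjusted p = 1.31e-21, and adjusted p = 0.126 with an estimated correlation). With detection in all 6 mice 13 members were left, of which 12 fell.

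Ly49 receptors, which bind MHC class I molecules, held the largest falls. Of 11 measured members 9 fell and 2 rose, also when adjusted over the list alone, with a median of -3.75. Klra4 fell by 5.07 (SE 0.62), Klra7 fell by 4.95 (SE 0.34), and Klra1 was at least 13.5-fold lower. Klra17 (2.41) and Klra2 (1.58) rose and were chosen after their values were seen. Ly49 genes are similar in sequence, so that values of single members are uncertain, and the cells that hold these transcripts were not identified. Camera called the list lower (adjusted p = 3.56e-07, and adjusted p = 0.263 with an estimated correlation). With detection in all 6 mice 3 members were left, which fell.

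Markers of NK maturation fell in part. Of 11 mature NK markers 4 fell (5 when adjusted over the list alone) and 7 did not pass. The mast cell protease gene Cma1 fell by 3.74, the pore-forming protein gene Prf1 fell by 3.70, the inhibitory receptor gene Klrg1 fell by 3.11 and Ahnak fell by 1.84. Itgam (-0.05), S1pr5 (-0.65) and Cx3cr1 (0.96) did not pass. Cx3cr1 and Spn (-0.36, chosen after its values were seen, not passed) are also in a list of non-classical monocyte genes used below. Which cells hold the transcripts of the mature list was not measured, so its counts do not show a shift in maturation. Cx3cr1 passed with the identifier block (adjusted p = 0.0309) and with the slide as a block (adjusted p = 0.0426), and S1pr5 with the mean of its probes (adjusted p = 0.0189). The mature list was lower by camera (adjusted p = 0.0252, and adjusted p = 0.303 with an estimated correlation). This call ended with the identifier block (adjusted p = 0.123), the slide as a block (0.129), detection in all 6 mice (0.147), the raised filter (0.0582) and without TLR7tg replicate 1 (0.0610), and adjusted p ran from 0.00892 to 0.147 over its alternatives. Its median was -0.36, and -0.20 with detection in all 6 mice, -0.13 with the mean of a gene's probes and -0.07 without a filter on dim probes.

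Of 15 immature NK markers 9 fell, 1 rose and 5 did not pass, and 12 fell and 1 rose when adjusted over the list alone. The co-stimulatory receptor gene Cd27 fell by 3.20 (SE 0.24), the chemokine gene Xcl1 fell by 2.83, Kit fell by 2.30 and the interleukin-7 receptor gene Il7r fell by 1.91. Ly6e, which is also an interferon-stimulated gene, rose by 1.12 and was chosen after its values were seen. The list was lower by camera (adjusted p = 1.32e-07, and adjusted p = 0.126 with an estimated correlation). Of 7 markers of tissue-resident NK cells and ILC1, 0 passed by limma, also when adjusted over the list alone, and 2 had an unadjusted p under 0.05 (camera adjusted p = 0.695, fry adjusted p = 0.386). The count was 1 higher and 1 lower with either block, and 1 lower with a trended and robust fit, with array weights and with the mean of a gene's probes. Tmem176b (0.88) passed with the identifier block (adjusted p = 0.0372) and with the slide as a block (adjusted p = 0.0465), and Tnfsf10, which encodes TRAIL, differed by -0.49 and did not pass.

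Genes of the killing machinery and of secreted factors moved both ways. Of 16 killing genes 4 fell and 1 rose (6 and 3 when adjusted over the list alone). The granule protease gene Ctsw fell by 4.14 (SE 0.56), the death ligand gene Fasl fell by 2.96 and the granzyme gene Gzmm fell by 2.32, while the lysosomal membrane gene Lamp2 (1.49, chosen after its values were seen) rose. The list did not pass by camera (adjusted p = 0.103) but did by fry (adjusted p = 0.0369) and, by camera, without TLR7tg replicate 3 (adjusted p = 0.0144, and from 0.0144 to 0.224 over its alternatives). The number of killing genes that rose was 0 without a filter on dim probes and without B6 replicate 1, B6 replicate 2, TLR7tg replicate 2 or TLR7tg replicate 3, 3 with the first technical array, array weights or the mean of a gene's probes, and 4 with either block or without TLR7tg replicate 1, and 7 fell with the identifier block. Of 19 cytokine and chemokine genes 6 rose and 5 fell (6 and 7 when adjusted over the list alone; camera adjusted p = 0.874). Ifng, encoding interferon gamma, fell by 2.56 (SE 0.34) and the chemokine gene Ccl5 fell by 3.20, whereas the inflammatory cytokine gene Il1b rose by 3.07 (SE 0.38) and the chemokine gene Cxcl9 rose by 2.59. Without a filter on dim probes 1 of these genes rose and 4 fell, and Cxcl9 did not pass (adjusted p = 0.0738), and with the identifier block 8 fell.

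Receptor and signalling genes also moved both ways, and which cells hold their transcripts was not measured. Of 20 cytokine receptor genes 7 fell and 4 rose (7 and 5 when adjusted over the list alone), and the list passed by fry (adjusted p = 0.0185) but not by camera (adjusted p = 0.571). The interleukin-18 receptor genes Il18r1 and Il18rap (-3.20 and -2.41) fell, as did Il2rb (-1.75), a receptor chain for interleukins 2 and 15. The 4 that rose were Il6ra (2.13), Csf2ra (1.93), Ifngr2 (1.41) and Csf2rb (1.01), chosen after their values were seen. Of 22 chemokine receptor and adhesion genes 5 fell (6 fell and 1 rose when adjusted over the list alone), among them Cxcr3 (-1.51), Selplg (-1.15) and Itga2, which was at least 2.46-fold lower. This list too passed by fry (adjusted p = 0.0392) but not by camera (adjusted p = 0.363). Of it 3 fell without a filter on dim probes and with detection in all 6 mice, 3 rose with either block, and 1 rose with array weights and without B6 replicate 1. With detection in all 6 mice 4 cytokine receptor genes fell. Of 18 adaptor and signalling genes 5 fell and 3 rose (7 and 5 when adjusted over the list alone). The kinase gene Zap70 (-3.59), the NKG2D adaptor gene Hcst (-2.61) and the CD3 zeta chain gene Cd247 (-2.49) fell. That list's median was 0.06, its mean -0.35 and its camera direction down (adjusted p = 0.774). The number that rose was 1 without a filter and without B6 replicate 1, B6 replicate 2 or TLR7tg replicate 2, and 5 with either block, and 3 fell with detection in all 6 mice. Of 10 checkpoint genes 2 fell, Cd96 (-1.89) and Tox (-1.76), and 3 rose, among them Cd274 (1.28), encoding PD-L1, and Havcr2 (1.25), encoding TIM-3 (3 and 3 when adjusted over the list alone). Its median was 0.13, its mean -0.08 and its camera direction up (adjusted p = 0.841), and with detection in all 6 mice 1 fell.

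Neutrophil genes rose the most of all lists by median. Of 16 measured markers 14 rose, also when adjusted over the list alone, and 2 did not pass, with a median difference of 2.93, 3.30 within the named slide and 2.84 among the other 4 mice. S100a8 and S100a9, which encode the subunits of calprotectin, rose by 5.07 (SE 0.84) and 4.73 (SE 0.89), and the granule protein genes Ltf and Lcn2 rose by 4.81 (SE 1.07) and 4.55. Csf3r, the receptor for granulocyte colony-stimulating factor, rose by 1.41. The signal of Ltf was 12.84, 14.37 and 9.11 in TLR7tg replicates 1, 2 and 3, and 7.67, 7.54 and 6.67 in those of B6. Camera called the list higher (adjusted p = 8.02e-11, and adjusted p = 0.248 with an estimated correlation). The number that rose was 5 without B6 replicate 2, 6 without B6 replicate 3, 7 without TLR7tg replicate 2, 3 of 24 without a filter on dim probes, where the median was 1.60, and 5 of 6 with detection in all 6 mice, where it was 2.11. Without B6 replicate 2, B6 replicate 3 or TLR7tg replicate 2, Ltf (adjusted p = 0.0606, 0.0588 and 0.0570), Lcn2 (0.0706, 0.0536 and 0.0801), Ngp (0.102, 0.0793 and 0.119) and Camp (0.0808, 0.0798 and 0.103) did not pass. Without a filter these, S100a8, S100a9 and Chil3 did not pass (adjusted p from 0.0529 to 0.182), and Ngp and Camp did not with a trended and robust fit (0.0705 and 0.0630).

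Monocyte and macrophage genes rose in part. Of 36 measured members 18 rose, 3 fell and 15 did not pass, and 25 rose and 3 fell when adjusted over the list alone. The median difference was 1.35, 1.46 within the named slide and 1.22 among the other 4 mice. The IgG receptor gene Fcgr4 rose by 3.43 (SE 0.45) to 14.11 ± 0.22 (SD, n = 3), the transcription factor gene Cebpb rose by 2.28 and Csf1r, the receptor for macrophage colony-stimulating factor, rose by 2.20 (SE 0.44). Vcam1, Slc40a1 and Mertk, genes known from red pulp macrophages of the spleen, fell (-2.23, -2.10 and -1.31), and the latter pair was chosen after the values were seen. C1qa (0.53) did not pass. Outside this list, the formyl peptide receptor gene Fpr2 rose by 4.04 (SE 0.43) and Smpdl3b rose by 3.69 (SE 0.31). Camera called the list higher (adjusted p = 1.14e-09, and adjusted p = 0.263 with an estimated correlation). The number that rose was 9 without TLR7tg replicate 2, where Csf1r did not pass (adjusted p = 0.0516), 10 without B6 replicate 2, 12 without B6 replicate 1 and 6 without a filter on dim probes, where Csf1r (0.0858) and Vcam1 (0.0528) did not pass. The number that fell was 2 without TLR7tg replicate 2, 1 without B6 replicate 2 and 0 without a filter.

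Innate sensing and interferon genes rose in part. Of 35 TLR and NF-kB signalling genes 13 rose and 0 fell (14 and 2 when adjusted over the list alone). Tlr13, a sensor of bacterial RNA, rose by 2.69 (SE 0.33), the inhibitory kinase gene Irak3 rose by 2.52 and Tlr2 rose by 2.09 (camera adjusted p = 4.08e-06, and adjusted p = 0.126 with an estimated correlation). Without a filter on dim probes 8 rose and 1 fell, 2 fell with either block, and 1 fell with array weights and without TLR7tg replicate 1. Of 36 interferon-stimulated genes 17 rose and 0 fell (23 and 1 when adjusted over the list alone), with a median of 0.72 (0.71 with genes at their bound). Oasl2 rose by 2.95, Ifi205 rose by 2.50, Ifit3 rose by 2.30 (SE 0.24) and Irf7, a transcription factor of interferon induction, rose by 1.22 (camera adjusted p = 8.02e-11, and adjusted p = 0.173 with an estimated correlation). Of 19 genes induced by interferon gamma 9 rose and 0 fell (12 and 0 when adjusted over the list alone), among them Gbp2 (2.14) and Igtp (1.24) (camera adjusted p = 4.08e-06, and adjusted p = 0.248 with an estimated correlation). The number of interferon-stimulated genes that rose was 9 without B6 replicate 2, 11 without B6 replicate 3 and 9 without a filter on dim probes, and that of genes induced by interferon gamma was 4 without a filter and without each mouse other than TLR7tg replicate 1. In the former list 1 gene fell with either block and with the mean of a gene's probes. With normexp at offset 16 the medians of these lists were 1.13 and 1.02, against 0.72 and 0.67. Irf7 did not pass without B6 replicate 2 (adjusted p = 0.0815) or B6 replicate 3 (0.0589), Gbp2 without TLR7tg replicate 2 (0.0512), and Oasl2, Cxcl9, Gbp2 and Irf7 without a filter (0.0516, 0.0738, 0.0741 and 0.0868).

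Few cell cycle genes rose. Of 56 measured members 3 rose, the transcription factor genes E2f1 (1.11) and E2f2 (1.28) and the mitotic checkpoint gene Bub1b (1.08), and 0 passed when adjusted over the list alone (16 had an unadjusted p under 0.05). The median was 0.45, and the camera call (adjusted p = 6.49e-07) was lost with an estimated correlation (adjusted p = 0.518) and by fry (adjusted p = 0.187). Without B6 replicate 1 (adjusted p = 0.0523, 0.0588 and 0.0926) and without B6 replicate 3 (0.0527, 0.0766 and 0.102) E2f1, E2f2 and Bub1b did not pass. E2f2 did not without B6 replicate 2 (0.0825), and E2f2 and Bub1b did not without TLR7tg replicate 2 (0.0543 and 0.101). All 3 did not without a filter on dim probes (0.0680, 0.123 and 0.128), nor did Bub1b with array weights (0.0541). The number that rose was 22 with the identifier block, 7 with the slide as a block, 6 without TLR7tg replicate 3 and 1 without TLR7tg replicate 2, where the median was 0.28, and the median was 0.24 without a filter and 0.73 with normexp at offset 16.

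Of 49 ribosomal protein genes 2 fell, Rps10 (-0.92) and Rpl12 (-0.95), also when adjusted over the list alone, with a median of -0.33. The camera call (adjusted p = 0.00650) was lost with an estimated correlation (adjusted p = 0.534), by fry (adjusted p = 0.0945) and without TLR7tg replicate 2 (adjusted p = 0.0953, and from 0.000229 to 0.0953 over its alternatives). Rpl12 did not pass without B6 replicate 2 (0.0651), B6 replicate 3 (0.0619) or TLR7tg replicate 2 (0.0550). The number that fell was 8 with the identifier block, 7 with the slide as a block, 5 without TLR7tg replicate 1, where the median was -0.20, and 1 without B6 replicate 2, B6 replicate 3 or TLR7tg replicate 2. Of 21 immediate early and heat shock genes, which respond to the handling of cells, 3 rose, Atf3 (1.58), Ier3 (0.82) and Jun (0.81), and Dusp2 (-1.06) fell (4 and 4 when adjusted over the list alone). The list did not pass by camera (adjusted p = 0.287) except without TLR7tg replicate 1 (adjusted p = 0.0320, and from 0.0320 to 0.843 over its alternatives). Jun did not pass without B6 replicate 1 (0.0834), B6 replicate 3 (0.101), TLR7tg replicate 2 (0.0859), TLR7tg replicate 3 (0.0748) or a filter on dim probes (0.0516), nor did Ier3 without B6 replicate 2 (0.0685), B6 replicate 3 (0.0754) or TLR7tg replicate 2 (0.0572), nor Dusp2 without B6 replicate 2 (0.0504). The list's median was 0.23, -0.15 within the named slide and 0.52 among the other 4 mice. Its counts ran from 0 to 7 higher and from 0 to 6 lower over the alternatives, with 7 and 6 under the identifier block, 6 and 1 without TLR7tg replicate 1, 2 and 2 without B6 replicate 1, 2 and 0 without B6 replicate 2, and 1 and 1 without B6 replicate 3 or TLR7tg replicate 2 and with detection in all 6 mice. They were 5 and 6 with the slide as a block, 3 and 4 with array weights, 3 and 3 with the mean of a gene's probes, and 0 and 1 with the raised filter.

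Markers of T cells fell in part, and 0 B cell markers passed. Of 17 T and NKT cell markers 8 fell and 0 rose (13 and 0 when adjusted over the list alone). The CD3 chain genes Cd3d, Cd3e and Cd3g differed by -2.42 (SE 0.21), -1.64 (SE 0.21) and -1.59 (SE 0.19), the chromatin organiser gene Satb1 fell by 2.56 and the adaptor gene Lat fell by 1.67. The median was -0.79 (-0.63 with genes at their bound), and camera called the list lower (adjusted p = 3.84e-07, and adjusted p = 0.126 with an estimated correlation). The median ran from -1.59 with the raised filter to -0.49 without a filter, and 13 fell with the slide as a block. Of 19 B cell markers 0 passed by limma, also when adjusted over the list alone, 4 had an unadjusted p under 0.05, and Cd79b, a chain of the B cell receptor, differed by 0.07. The B cell list did not pass by camera (adjusted p = 0.103) or fry (adjusted p = 0.473). It passed by camera with the identifier block (adjusted p = 0.0369) and without B6 replicate 1 (0.0364), B6 replicate 2 (0.0253) or TLR7tg replicate 3 (0.00418), with a range from 0.00418 to 0.749 over its alternatives, and Fcmr (-0.67) passed with the identifier block (0.0155). Its counts were 4 higher and 2 lower with that block, 2 and 1 with the slide as a block, and 1 and 0 with array weights and without B6 replicate 1. Of 9 plasma cell markers 2 rose (4 when adjusted over the list alone), the secretory transcription factor gene Xbp1 by 1.39 (SE 0.17) and the immunoglobulin gene Ighg1 by 1.41 (SE 0.31). The plasma cell list was higher by camera (adjusted p = 0.000956, and adjusted p = 0.318 with an estimated correlation), a call lost by fry (adjusted p = 0.0644) and with the raised filter (adjusted p = 0.0921). Its median was 0.73 (0.64 with genes at their bound), 1.47 within the named slide and 0.38 among the other 4 mice. Ighg1 did not pass without B6 replicate 2 (0.0507), TLR7tg replicate 3 (0.0574) or a filter on dim probes (0.0951). The number of plasma cell markers that rose was 1 without B6 replicate 2 and with each other filter, and 4 with array weights or either block. The median was 0.39 without TLR7tg replicate 1 and 1.22 with normexp at offset 16.

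Of 20 dendritic cell and antigen presentation genes 3 rose (6 when adjusted over the list alone), Cd40 (1.19), Cst3 (1.20) and Ciita (0.64), while H2-Aa (0.32) and Itgax (0.18), encoding CD11c, did not pass. Camera called the list higher (adjusted p = 0.000273, and adjusted p = 0.263 with an estimated correlation). With either block 8 rose, and the median was 0.50, and 0.31 without a filter on dim probes. Ciita, the regulator of MHC class II genes, did not pass without any one of the 6 mice (adjusted p from 0.0507 without TLR7tg replicate 3 to 0.127 without B6 replicate 2), nor with normexp, a trended and robust fit or the mean of its probes (from 0.0508 to 0.0921). Of 8 plasmacytoid dendritic cell markers Pltp (1.36) rose and Cox6a2 (-0.82) fell (2 and 1 when adjusted over the list alone; camera adjusted p = 0.515). Pltp did not pass without B6 replicate 2 (0.0697) or TLR7tg replicate 2 (0.0529), nor did Cox6a2 without B6 replicate 1 (0.0816), B6 replicate 2 (0.0520), B6 replicate 3 (0.0954) or TLR7tg replicate 2 (0.0804), nor either gene without a filter on dim probes (0.0723 and 0.0529). Hence 0 of this list passed without B6 replicate 2 or TLR7tg replicate 2. The number that rose was 0 with detection in all 6 mice and the raised filter, and 2 with normexp, a trended and robust fit, array weights, the mean of a gene's probes or either block.

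Of 15 erythroid markers 5 rose (10 rose and 1 fell when adjusted over the list alone), with a median of 0.77 (0.67 with genes at their bound). The globin gene Hba-a1 rose by 3.03 (SE 0.47) to 14.07 ± 0.86 (SD, n = 3), and Alas2, an enzyme of haem synthesis in red cell precursors, rose by 1.64 (SE 0.25). Camera called the list higher (adjusted p = 5.69e-06, and adjusted p = 0.263 with an estimated correlation). The number that rose was 2 without B6 replicate 1 or B6 replicate 3, 3 without B6 replicate 2, TLR7tg replicate 2 or TLR7tg replicate 3, 9 without TLR7tg replicate 1, 3 without a filter on dim probes, 2 with detection in all 6 mice, 12 with the identifier block and 11 with the slide as a block, and 1 fell with either block. The median was 1.22 with normexp at offset 16. Of 5 mast cell and basophil markers 2 rose (3 when adjusted over the list alone), the histamine synthesis gene Hdc by 2.20 (SE 0.48) and the basophil protease gene Prss34, at least 2.92-fold higher. Camera called that list higher (adjusted p = 0.00252, and adjusted p = 0.303 with an estimated correlation), and fry did not (adjusted p = 0.0644). Hdc did not pass without B6 replicate 2 (0.0506) or B6 replicate 3 (0.0555), nor did Prss34 without any one of B6 replicates 1, 2 and 3 and TLR7tg replicate 2 (0.0504, 0.0875, 0.0616 and 0.0841), nor either gene without a filter on dim probes (0.111 and 0.136). With the identifier block 4 of this list rose. Its median was 0.72, and 1.21 with normexp at offset 16, 0.48 without TLR7tg replicate 2 and 0.41 without a filter. Of 8 platelet markers 3 fell and 2 rose (3 and 3 when adjusted over the list alone). The platelet receptor gene Gp1bb was at least 3.02-fold lower and F2rl2 fell by 1.21 (SE 0.19). The 2 that rose, Ppbp and Tubb1 (at least 1.35-fold and at least 1.30-fold higher), did not pass without B6 replicate 1 (0.0537 and 0.0894), B6 replicate 2 (0.104 and 0.106), B6 replicate 3 (0.0980 and 0.0899), TLR7tg replicate 2 (0.0669 and 0.0788) or TLR7tg replicate 3 (0.0754 and 0.0568), nor did Tubb1 without TLR7tg replicate 1 (0.0541). The platelet list's median was 0.08, its mean -0.22 and its camera direction down (adjusted p = 0.908), and the direction turned with normexp at offset 16. Of 3 sex-linked genes 0 passed by limma, also when adjusted over the list alone, and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.876, fry adjusted p = 0.473). On the brightest probe of each gene, Xist lay above the detection level in 1 B6 mouse and 2 TLR7tg mice, and the Y-linked genes Eif2s3y and Kdm5d in 2 B6 mice and 1 TLR7tg mouse (another kept Xist probe did so in 2 mice of each group), so that these genes were not balanced between the groups.

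**Figure D2:**
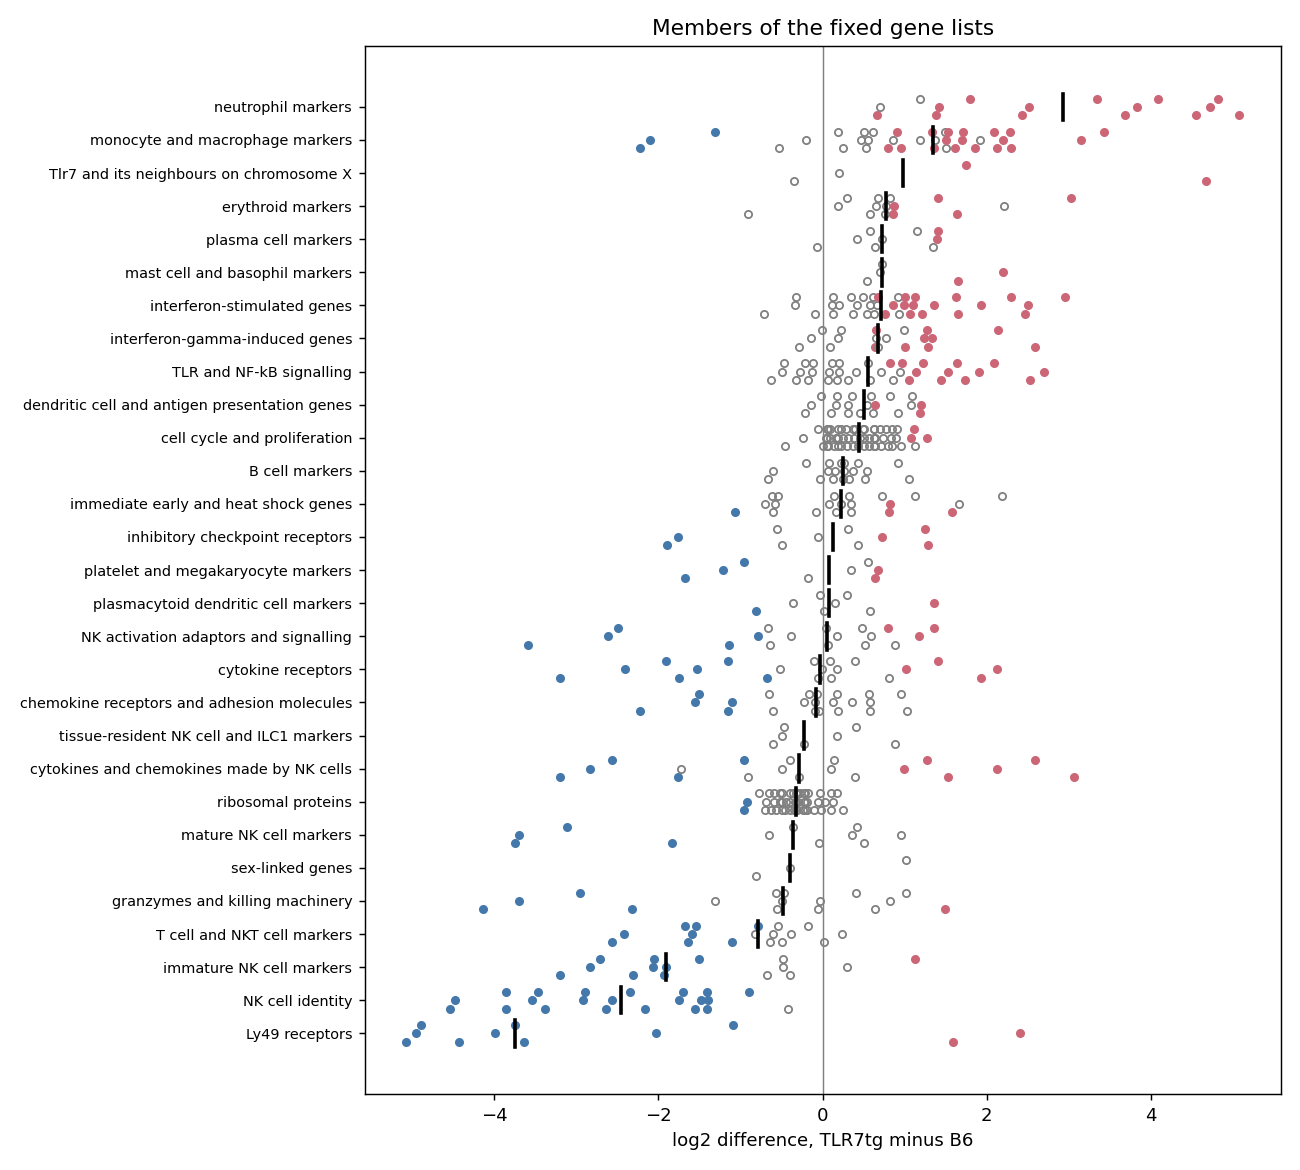
Log2 difference between TLR7tg and B6 (x axis) of each measured member of the 29 gene lists (y axis), with genes past the threshold filled in red (higher) or blue (lower), other genes open, and black bars at the list medians. The medians run from -3.75 for Ly49 receptors and -2.45 for NK cell identity to 1.35 for monocyte and macrophage markers and 2.93 for neutrophil markers.

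By camera 11 lists were higher and 6 lower. With an estimated correlation 0 of the 29 lists passed, the lowest adjusted p being 0.126, and by fry 16 passed.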

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

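Normexp on the deposited values, detection in all 6 mice and the raised filter were chosen after the data were seen. The count of genes higher in TLR7tg was 459 without a filter, where more probes were tested, and 1118 with neighbouring mouse identifiers as a block. That of genes lower in TLR7tg was 1166 with this block and 1083 with the slide as a block. The cause was not tested for the blocks, under each of which all 1349 genes remained called. Leaving out each mouse gave 422 to 754 and 340 to 629 of these genes, 690 to 924 genes changed at least 2-fold, 16 to 19 called gene lists and a Tlr7 difference of 4.34 to 5.05. Called lists numbered 17, 0 with an estimated correlation, and 14 to 19 under the alternatives to the probe test. Tlr7 passed under each alternative (adjusted p from 2.78e-05 to 0.00526). Over the named genes and settings other than leaving out a mouse, direction and side of the threshold were kept 1230 times, a call ended 33 times and began 6 times, and leaving out a mouse kept them 637 times and ended a call 76 times. Those that turned were not past the threshold. With array weights they were gene: Cd79b (-0.037) and gene: Itgam (0.069). Leaving out each mouse, gene: Cd79b ran from -0.32 to 0.31, gene: Itgam from -0.25 to 0.17, gene: Itgax from -0.052 to 0.35, gene: H2-Aa from -0.25 to 0.63, the tissue-resident list from -0.37 to -0.071 and the sex-linked list from -0.74 to -0.11. For lists it was camera's or fry's direction that turned, and the values are medians. These were the platelet and megakaryocyte markers with normexp at offset 16 (0.17) and without a filter (0.072), the sex-linked genes without a filter (-0.11), the inhibitory checkpoint receptors by fry (0.13), the plasmacytoid dendritic cell markers with the raised filter (0.0125) and with detection in all 6 mice (0.0125), and in the last setting also the cytokines (0.098), cytokine receptors (-0.0079) and adaptors (0.18). The median over all genes was -0.06, and -0.11 with the raised filter. Not run were median scaling and a stricter detection p on the scanner signals, since the arrays of 4 mice are not named, and the authors' values without background correction are themselves the tested values. Signal over background limits dim genes: 57 called genes lay below the detection level in all TLR7tg mice and 69 in all B6 mice, and these have only a bound.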

Other observations

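The families, the list of non-classical monocyte genes and all tests here other than those of the second myeloid list and of the splits were chosen after the results were seen. Of 217 families of at least 6 measured genes that share a symbol stem, 5 passed camera at the preset correlation, and 0 passed with an estimated correlation (lowest adjusted p = 0.996). Gimap genes, which encode GTPases of lymphocytes, fell in all 6 measured members, with a median of -2.20 (adjusted p = 2.74e-07). Among them Gimap8 fell by 3.05 and Gimap1 fell by 2.51. Toll-like receptor genes rose in 7 of 8 members (adjusted p = 2.87e-06), which include the transgene Tlr7 itself and its neighbour Tlr8, and in 5 of 6 without these (adjusted p = 0.000466), and Tlr5 (0.21) did not pass. Of 16 Clec lectin genes 6 rose and 0 fell (adjusted p = 0.00182), among them Clec4a3 (2.60), Clec4a1 (2.55) and Clec4e (1.82). Of 6 Csf genes 5 rose (adjusted p = 0.0108), all of them receptor genes such as Csf2ra (1.93), and the cytokine gene Csf2 (-0.50) did not pass. The fifth family was that of the Ly49 genes (adjusted p = 5.32e-06).

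In a list of genes known from non-classical monocytes 12 of 17 measured members rose, 0 fell and 5 did not pass, against 710 rises among all 9173 genes, and no enrichment test was made. Its median was 2.21, and 7 of the 17 are also in the lists fixed in advance. Eno3 rose by 2.94 (SE 0.41), Gngt2 rose by 2.82 (SE 0.45), Ace rose by 2.31 (SE 0.43), Treml4 rose by 2.21 (SE 0.31) and Pou2f2 rose by 1.86 (SE 0.26). Cd300e (0.60), Hes1 (0.74), Itgal (1.03), Cx3cr1 (0.96) and Spn (-0.36) did not pass.

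Most NK identity genes fell, while most neutrophil markers and part of the monocyte genes rose. The tables argue against a lower share of NK cells with all other cells in unchanged proportion, since the neutrophil median exceeded the B cell median by 2.69 (two-sided permutation over list members, p = 1e-05, the smallest the permutations can give) and the monocyte median exceeded it by 1.11 (p = 0.00057). Whether red pulp macrophages were the source of the monocyte rise stays undecided. The falls of Vcam1, Slc40a1 and Mertk were seen before the test was chosen. The median over 7 genes of these macrophages (6 in the fixed lists) differed by -2.03 from that of the 30 other monocyte genes (permutation p = 9e-05, SD of the 7 genes 1.18). It differed by -2.37 to -1.66 over the alternatives. This permutation too was over list members, so its p-value does not measure the spread between mice. Of the 7, Spic (0.51), Hmox1 (0.47), Itgad (0.22) and Axl (-0.53) did not pass. These 7 genes moved both ways, with a median of -0.53 (-0.84 to -0.16 over the alternatives), and 3 fell and 0 rose, where 0 fell without a filter and 1 fell without B6 replicate 2. The tables argue too against the quantile normalisation as the source in replicate 1, where the median NK identity ratio on the raw signals was -2.98. The tables argue as well against a difference in sex between the groups, read from the brightest Xist probe, as the whole source. With Xist above or below the detection level as a block the medians were -2.51 for NK identity, 2.82 for neutrophil and 1.104 for monocyte genes. They were -2.37, 2.80 and 1.30 among the 1 B6 and 2 TLR7tg mice above that level. Among the 2 B6 mice and 1 TLR7tg mouse below it they were -2.66, 2.58 and 0.99. Each of these medians thus rests on 1 mouse in 1 of the groups. Another kept Xist probe put B6 replicate 3 above the level too (7.38), and that grouping was not tested. On the other Xist probes this mouse lay at 6.54, 6.51 and 6.64. On their brightest probes its Eif2s3y and Kdm5d signals were 9.10 and 7.87. These Y-linked genes lay above the level in just the mice where the brightest Xist probe lay below it. For single genes sex stays open, since 627 rose and 554 fell with the block on the brightest Xist probe, and 1108 of the 1349 calls were kept. A larger share of other myeloid cells in the TLR7tg preparations is a candidate explanation, since 81.8% of 22 genes of a second myeloid list rose. Of these genes 0 are in the fixed lists, and all 22 lay above the detection level on average in B6 too. A gate on NK1.1, if used, would be meant to remove such cells. How the cells were isolated is not given, and the sample labels name NK cells for B6 and NK1.1+ cells for TLR7tg. A difference in isolation thus cannot be told apart from one of genotype. The brightest genes of the second myeloid list in TLR7tg were Psap (12.82 in B6, 13.74 in TLR7tg) and Lgals3 (11.03 and 13.16), and signals of different probes do not rank abundance. A different make-up or programme of the cells labelled NK1.1+ from TLR7tg mice stays open as the biological explanation. It was not tested, because arrays of pooled cells do not show which cell holds a transcript. NK1.1+ is taken from the labels here, and the mean signal of Klrb1c, the gene of NK1.1, was 9.64 in B6 and 7.47 in TLR7tg.

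Between the genotypes 1349 genes differed, and the highest count in the other splits of the 6 mice into 3 and 3 was 0. The real split was the 1 of 10 with as many genes. With 10 splits the share is never under 0.1, too few for a test of chance.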
